A study of Drosophila melanogaster with 6 samples.

How the data were processed

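Malpighian tubules were dissected from flies that carried esg-GAL4, UAS-GFP and tub-GAL80ts, without (control) or with UAS-yki3SA (tumour), 3 libraries each. Per the labels, RNA with an integrity number above 7 was selected for poly-A transcripts, made into TruSeq libraries and sequenced on an Illumina HiSeq instrument. The authors deposited 1 table of unnormalised read counts per gene, in counts, with 1 column per library. The submitters' processing notes name TopHat, Cufflinks and HTSeq with no version and no role for each, and the genome build, the annotation release and the strandedness of counting are not given in the sources used here, so counts of overlapping or antisense genes are uncertain. The table held 17611 genes, of which 59 had an identifier without a symbol and 3658 had 0 counts in every library. Coordinates were taken from the Ensembl BDGP6 annotation by FlyBase gene identifier for 17552 genes and do not describe the build on which reads were counted. Raw reads were not analysed here.

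Library totals lay between 34640437 and 49338340 counts. A count of 0 allows up to 3 counts, or between 0.0608 and 0.0866 CPM; this limit and count intervals cover counting error only, since reads are not independent molecules. Ratios of genes with 1 to 3 counts in a group have an exact 95% interval. CPM are scaled by TMM and given as mean ± SD (n = 3).

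Analysis used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Genes were filtered with filterByExpr by group (minimum count 10, minimum total count 15), which left 9789. Tumour was compared with control by the robust quasi-likelihood test of edgeR after TMM normalisation, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of F. The biological coefficient of variation was 30.8%. Principal components used log2 CPM with a prior count of 2.

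Before the data were examined, 40 gene lists were fixed, and 16 members had no match in the table. Of these lists 11 hold markers of cell types. They cover the tubule's own principal and stellate cells, progenitors (renal and intestinal stem cells in 1 list), and other cells that a dissection can carry. Lists with at least 3 tested members, 39 in all, were tested with camera at a preset correlation of 0.01, adjusted over lists, and also with an estimated correlation and with fry, which asks whether the genes of a list move one way and compares them with no other genes. A rule fixed before the data were examined named genes: yki and esg; the 12 genes with the largest rise and the 12 with the largest fall that passed, had a mean log2 CPM of at least 1 and no overlap between groups; up to 4 genes with the smallest adjusted p per list, or 2 where none passed; TkR99D, ITP, Nos, Lkr, CapaR, Pvr, Socs36E, ImpL2 and Uro; and the 3 most expressed genes per marker list. The rule gave 179 genes. Those shown as examples of a list were picked from them after their values were seen, preferring genes whose calls held without any 1 library.

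Alternatives fixed before the data were examined were RLE and upper-quartile normalisation, no filter, a filter of 5 CPM in 3 libraries, a replicate block, leaving out the 20 most abundant genes, leaving out each library, DESeq2, limma-voom, a test against a fold of 1.5, a threshold of 0.01, an estimated correlation and fry. Added after the data were seen were library totals alone as the scaling, leaving out the midgut and the eggshell lists, list medians over members above 0 in every library, and member counts without each library and by other tools. The comparison of metabolic and ribosomal genes with genes of like expression, those within 100 ranks on each side, replaced a count of lower genes over 6 scalings after that count and the fold changes were seen; its bounds were set before its own value was, and no other window was run. Tested on simulated data of the same size and spread, with 100 genes changed at each size among 9789, edgeR recovered 46% of 2-fold and 80% of 4-fold changes, with 12 false among 138 calls. DESeq2 recovered 54% and 87% with 40 false calls, and limma-voom 46% and 78% with 13. The 200 genes changed there are far fewer than the 2726 that passed in the data. The adjusted p depends on that share, so these rates need not hold for the data.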

Results

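RNA was sequenced from the Malpighian tubules, the renal organs of the fly, of Drosophila melanogaster with and without gut tumours. Tumours were induced by yki3SA, an active form of the growth regulator Yorkie, expressed under esg-GAL4 in intestinal progenitor cells. Control flies carried the same driver without the yki3SA transgene. Virgin flies of both groups were held at 18 °C for 6 to 8 days and then at 29 °C for 8 days, and 80 tubules of each genotype were lysed. Each group had 3 libraries. The libraries of control replicates 1, 2 and 3 held 45728599, 39213686 and 36088638 counts, and those of tumour replicates 1, 2 and 3 held 34640437, 40867555 and 49338340. At this depth 3 counts in a library, the limit that a count of 0 allows, correspond to between 0.0608 and 0.0866 CPM, the per-library count unit used throughout. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The 20 most abundant genes held 21.0% ± 0.50 of counts in control and 16.63% ± 0.694 in tumour libraries (SD, n = 3 each), and mitochondrially encoded transcripts 7.04% ± 0.881 and 4.82% ± 0.424.

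The transcript of yki, the gene carried by the transgene, was at 79.6, 63.5, 79.4 CPM in the control and 84.4, 90.9, 76.9 CPM in the tumour libraries. The log2 fold change of tumour over control was 0.18 ± 0.13 (SE), which did not pass the test (adjusted p = 0.331, edgeR quasi-likelihood test); with library totals alone as the scaling it was 0.47 and passed (adjusted p = 0.015). The transgene is driven in esg-positive cells, and esg itself was at 5.78 ± 0.298 CPM in control and 3.75 ± 2.63 CPM in tumour libraries (SD, n = 3 each, adjusted p = 0.339). The log2 fold change of esg was -0.62 ± 0.45; without tumour replicate 2, where esg was at 6.78 CPM, it was -1.37 and passed (adjusted p = 0.0195, against 0.0195 to 0.904 over all alternatives), and it was -0.41 without tumour replicate 1 and -0.37 without tumour replicate 3. The level of yki in tubule RNA therefore gives no check of the genotype labels.

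The comparison of tumour with control tubules asks which renal transcripts differ in flies that bear a gut tumour. The transcript of esg was present in tubule RNA. A direct effect of yki3SA in esg-positive tubule cells therefore cannot be told apart from an effect of the gut tumour. Of 9789 genes tested, 2726 passed an adjusted p of 0.05, of which 1453 rose and 1273 fell in tumour tubules. The change was 2-fold or more for 464 of the genes that rose and 679 of those that fell, and 4-fold or more for 173 and 308. The 12 genes with the largest rise were Nazo, AttD, Nepl9, CG14275, DptA, edin, CG44098, CG14302, Dro, thw, Erasp and Syt4. Nazo (FBgn0037562, chromosome 3R, 8287876 to 8288613) rose from 1.03 ± 0.40 to 238 ± 54.4 CPM (log2 fold change 7.85 ± 0.33, adjusted p = 1.65e-05). AttD, which encodes an attacin, and DptA, which encodes diptericin, are antibacterial peptide genes: AttD rose from 0.40 ± 0.146 to 81.4 ± 6.5 CPM and DptA from 2.92 ± 1.33 to 296 ± 65 CPM. Erasp rose from 0.609 ± 0.156 to 21.7 ± 7.18 CPM. The exons of CG44098 overlap those of atms, so its counts are uncertain, and the call of Dro, which encodes drosocin, was lost without control replicate 2 (adjusted p = 0.0540, against 0.000105 to 0.0540 over all alternatives).

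The 12 genes with the largest fall were CAH5, mag, lncRNA:CR45570, epsilonTry, LManVI, LysE, CG6295, LysC, LysB, LManV, CG12374 and Cp38. CAH5 (FBgn0040629, chromosome 3R, 31262598 to 31263878), a carbonic anhydrase gene, fell from 38.5 ± 16.7 to 0.0363 ± 0.0629 CPM (SD, n = 3 each, adjusted p = 4.87e-04). For mag the tumour libraries held 1 count in all, and the ratio of control to tumour was 829 (95% exact interval 148 to 32792), counting error only. The digestive enzyme genes epsilonTry, LManVI and LManV and the lysozyme genes LysB, LysC and LysE had a mean of at most 0.238 ± 0.27 CPM in tumour libraries, a level at which the size of the fold change depends on single libraries. LysC overlaps LysD, the lysozyme genes are close copies, and lncRNA:CR45570 overlaps a roo transposable element, so the counts of these genes are uncertain. The call of LysB was lost without tumour replicate 3 (adjusted p = 0.0528, against 0.000103 to 0.0528 over all alternatives). The call of the chorion gene Cp38 was lost without control replicate 1 (adjusted p = 0.0509), control replicate 2 (0.0685) or tumour replicate 3 (0.0814), against 0.000277 to 0.130 over all alternatives.

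Transcripts of renal transport fell more often than they rose. Of 31 tested genes of ion and water transport, 11 fell and 3 rose, and the counts were 11 and 3 when adjusted over the list alone (camera, adjusted p = 0.00366; adjusted p = 0.50 with an estimated correlation). With library totals alone as the scaling, 7 fell and 6 rose, and without control replicate 3 only 1 rose. Irk3, an inward-rectifier potassium channel gene, fell from 2786 ± 184 to 999.6 ± 65.3 CPM (log2 fold change -1.48 ± 0.12, adjusted p = 1.76e-04), with exons that overlap Grip71. Of the aquaglyceroporin-related genes, Eglp2 fell 6.58-fold and Eglp4 4.31-fold (adjusted p = 3.04e-04 and 2.27e-04). The cation-chloride cotransporter gene NKCC (FBgn0051547, chromosome 3R, 5489505 to 5502702) moved the other way and rose in all 3 tumour libraries, from 28.8 ± 4.21 to 319.6 ± 48.9 CPM (log2 fold change 3.47 ± 0.17, adjusted p = 1.93e-05). NaPi-T, a phosphate transporter gene, fell 2.47-fold (adjusted p = 0.00135). Among 19 organic solute transporters 8 fell and 1 rose, or 11 and 2 adjusted over the list alone (camera, adjusted p = 0.00425; adjusted p = 0.50 with an estimated correlation). In this list 0 rose in the edgeR test without control replicate 1, control replicate 3 or tumour replicate 3. Scaled by library totals alone, 6 fell and 2 rose. In the same libraries 17 of 31 midgut, 4 of 11 fat body and 10 of 18 germline and eggshell markers fell. Oatp58Da fell 2.88-fold, Oatp58Db 2.19-fold and the multidrug transporter gene Mdr65 3.47-fold. Of 25 subunits of the V-ATPase, the proton pump that energises secretion, 3 rose and 3 fell, the same counts adjusted over the list alone, and the list did not pass (camera, adjusted p = 0.683). The subunits that rose numbered 7 with library totals alone. Vha26 fell from 3072 ± 202 to 2069 ± 135 CPM and VhaPPA1-1 from 1647 ± 99.6 to 1027 ± 106 CPM, while Vha68-1 rose from 14.2 ± 2.38 to 27.3 ± 2.42 CPM.

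Receptors through which hormones act on the tubule gave 1 rise and 5 falls among 17 tested, or 3 and 5 adjusted over the list alone, and the list did not pass (camera, adjusted p = 0.234). Of these genes 3 fell without control replicate 3, tumour replicate 1 or tumour replicate 3, and with library totals alone 1 fell and 3 rose. NPFR, the neuropeptide F receptor gene, fell from 20.8 ± 3.71 to 3.61 ± 0.567 CPM (log2 fold change -2.52 ± 0.21, adjusted p = 1.85e-04). CapaR, the receptor gene for Capa peptides, fell 1.42-fold (adjusted p = 0.0116), a call lost with library totals alone (0.127) and against a fold of 1.5 (0.99999, with 0.00059 to 0.99999 over all alternatives). Lkr, the leucokinin receptor gene of stellate cells, passed narrowly (log2 fold change -0.46 ± 0.14, adjusted p = 0.0451), and its call was lost in 5 of the 6 fits that left out 1 library, where the adjusted p reached 0.138, and with library totals alone (0.364, with 0.0138 to 0.99999 over all alternatives). Pvr, the receptor tyrosine kinase gene for Pvf ligands, fell (log2 fold change -0.83 ± 0.21, adjusted p = 0.0237), a call lost without control replicate 3 (0.0621), tumour replicate 1 (0.0802) or tumour replicate 3 (0.0658) or with library totals alone (0.0810, with 0.000314 to 0.289 over all alternatives). TkR99D, a tachykinin receptor gene, was at 7.35 ± 1.89 CPM in control and 8.41 ± 3.05 CPM in tumour libraries (adjusted p = 0.692). The transcript of ITP, the ion transport peptide, rose from 37.4 ± 6.64 to 69.4 ± 11.2 CPM (log2 fold change 0.89 ± 0.17, adjusted p = 0.00761), with exons that overlap CG4622. ITP is no receptor gene and belongs to the list of enteroendocrine markers, cells that a dissection can carry. In that list 3 rose and 1 fell among 7, so RNA of such cells cannot be told apart from the tubule's own. Of 16 genes of nitric oxide and cyclic nucleotide signalling 1 rose and 2 fell, the same counts adjusted over the list alone, and Nos was at 0.399 ± 0.21 and 0.446 ± 0.191 CPM in the respective groups (adjusted p = 0.892). With library totals alone 4 genes of the nitric oxide list rose and 0 fell in the edgeR test. Between 0 and 3 fell, and 0 or 1 rose, without 1 library; 0 fell without control replicate 1, and 0 rose without control replicate 3 or tumour replicate 2.

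**Figure D1:**
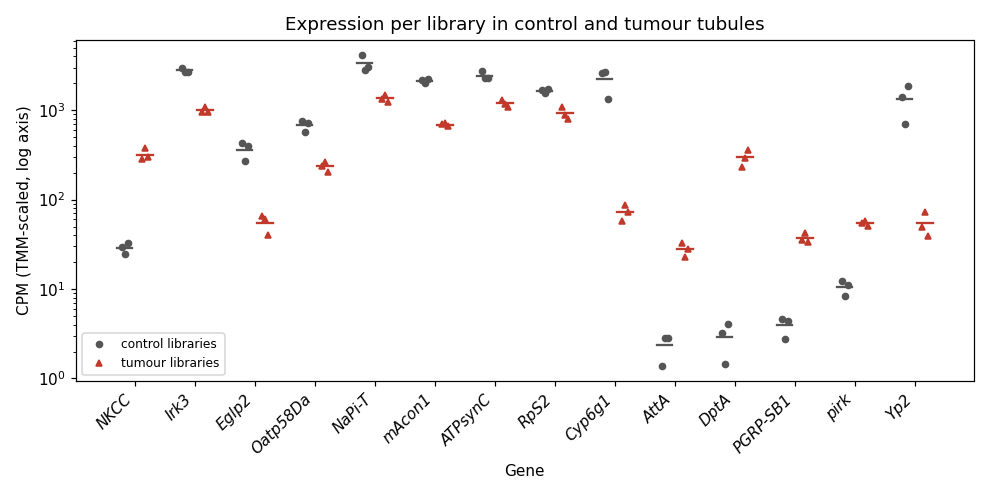
Expression of 14 genes in each of the 6 libraries, in TMM-scaled CPM on a log axis; circles are control and triangles tumour libraries, and bars are group means (n = 3 each). For each gene shown every tumour library lies beyond every control library.

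All genes of the TCA cycle, oxidative phosphorylation and fatty acid oxidation lists that passed the edgeR test fell, with TMM scaling and all 6 libraries. Of 18 tested genes of the TCA cycle, 16 fell and 0 rose (17 and 0 adjusted over the list alone), with a median log2 fold change of -0.72. The aconitase gene mAcon1 (FBgn0010100, chromosome 2L, 21168570 to 21173185) fell from 2142 ± 138 to 691 ± 24.5 CPM (log2 fold change -1.63 ± 0.12, adjusted p = 9.89e-05), the succinate dehydrogenase gene SdhA 2.33-fold and the pyruvate carboxylase gene PCB 2.55-fold, and the exons of all 3 overlap other genes. Of 62 nuclear genes of oxidative phosphorylation, 45 fell and 0 rose (50 and 0 adjusted over the list alone), with a median of -0.54. ATPsynC and blw, which encode subunits of ATP synthase, fell 2.04-fold and 1.88-fold. Of 14 genes of fatty acid oxidation 6 fell, among them Etf-QO (1.94-fold) and Echs1 (2.06-fold), and 10 did so adjusted over the list alone. Of 85 genes of cytosolic ribosomal proteins, 67 fell and 0 rose (79 and 2 adjusted over the list alone), with a median of -0.53, and RpS2 fell 1.79-fold. In the camera test the adjusted p was 3.13e-10 for the TCA cycle, 2.35e-11 for oxidative phosphorylation, 0.00366 for fatty acid oxidation and 9.15e-13 for ribosomal proteins. With an estimated correlation the adjusted p was 0.50 for each of the first 3 of these lists and 0.516 for ribosomal proteins. With library totals alone as the scaling, 60 of the 165 genes of the TCA cycle, oxidative phosphorylation and ribosomal protein lists fell and 3 rose, against 128 and 0 with TMM scaling. The number of ribosomal protein genes that fell was 34 without control replicate 1, 26 without control replicate 3, 17 without tumour replicate 2 and 25 without tumour replicate 3. For oxidative phosphorylation it was 28, and for fatty acid oxidation 3, without control replicate 1 or tumour replicate 3, and without tumour replicate 2 it was 27 and 2. In the same libraries the transcripts of midgut, fat body, germline and eggshell marker genes held 5.59% of control and 2.56% of tumour counts. Without Mur18B, the most abundant of them, they held 0.460% and 0.0493%. Glycolysis genes gave 3 falls and 0 rises among 13 tested, Hex-C among them (1.95-fold), and of 72 genes of mitochondrial ribosomal proteins 8 fell; neither list passed (camera, adjusted p = 0.16 and 0.0836). Adjusted over the list alone, 1 glycolysis gene and 2 genes of mitochondrial ribosomal proteins fell. Only 1 glycolysis gene fell in each fit without 1 library except that without control replicate 3, the count for mitochondrial ribosomal proteins lay between 2 and 13 over those fits, and with library totals alone 10 of the latter rose and 1 fell. On that scaling 2 glycolysis genes rose and 1 fell, and 1 gene of fatty acid oxidation rose and 3 fell. Of 22 genes of lipid synthesis and storage 8 fell, including the perilipin gene Lsd-2 (1.85-fold), and 1, the desaturase gene Desat1, rose (1.48-fold; camera, adjusted p = 0.107). The counts of lipid genes were the same adjusted over the list alone. Of the lipid genes 5 fell without control replicate 1 or 2, and 4 fell without control replicate 3, tumour replicate 1 or tumour replicate 3. Scaled by library totals alone, 4 lipid genes rose and 4 fell.

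Detoxification enzymes that changed mostly fell. Of 76 cytochrome P450 genes 24 fell and 6 rose, of 30 glutathione S-transferase genes 11 fell and 1 rose, and of 30 UDP-glycosyltransferase genes 10 fell and 3 rose. Adjusted over the list alone the falls numbered 25, 12 and 12. The camera test gave an adjusted p of 0.00187, 0.00153 and 9.21e-05 for the 3 lists, and an adjusted p of 0.50 for each with an estimated correlation. With library totals alone 19 P450, 8 glutathione S-transferase and 10 UDP-glycosyltransferase genes fell and 13, 3 and 5 rose, and 7 glutathione S-transferase genes fell without control replicate 2, tumour replicate 2 or tumour replicate 3. In the same libraries 17 of 31 midgut enzyme genes fell. Cyp6g1 (FBgn0025454, chromosome 2R, 12185667 to 12188431), known for its part in insecticide resistance, fell from 2206 ± 742 to 72.4 ± 14.9 CPM (log2 fold change -4.93 ± 0.33, adjusted p = 1.18e-04), and Cyp6a18 from 1437 ± 237 to 445 ± 51.8 CPM. GstE10 fell 2.68-fold and GstZ2 22.5-fold. Ugt37B1 fell from 38.7 ± 11.6 to 0.926 ± 0.32 CPM and Ugt35C1 from 181 ± 58.6 to 9.35 ± 3.1 CPM. These families hold close copies, and Cyp6g1 and GstE10 overlap neighbouring members, so how reads were split between copies is uncertain. Any other difference between the genotypes is confounded with the tumour for these genes too, and was not tested. Of 14 antioxidant genes 2 rose and 4 fell, including Prx3 (2.36-fold) and Gclc (2.02-fold), and 0 of 17 heat shock and chaperone genes passed the edgeR test, with 2 at an unadjusted p under 0.05, 1 higher and 1 lower by DESeq2 and 0 by limma-voom. Purine metabolism gave 5 rises and 3 falls among 17 genes, but leaving out any library other than control replicate 2 gave between 1 and 3 rises. Adgf-A, an adenosine deaminase gene that overlaps Adgf-A2, rose 7.59-fold and Prat2 fell 4.03-fold. The urate oxidase gene Uro was at 1772 ± 203 CPM in control and 1276 ± 374 CPM in tumour libraries (adjusted p = 0.15). Of 19 metal-handling genes 2 rose and 4 fell, with Tsf1 lower by 5.99-fold, and of 11 genes of pigment pathways 1 rose and 3 fell. Of the metal-handling genes 2 fell without control replicate 1 or tumour replicate 3, and 0 rose without tumour replicate 1 or 2. Scaled by library totals alone, 9 purine, 7 metal, 4 antioxidant, 4 pigment and 2 heat shock genes rose and 2, 4, 3, 3 and 0 fell in the edgeR test; 1 heat shock gene rose without tumour replicate 3. Adjusted over the list alone, 7 purine genes rose and 3 fell, and the counts of the antioxidant, heat shock, metal and pigment lists were the same. None of these last 5 lists passed (camera, adjusted p = 0.234, 0.967, 0.405, 0.192 and 0.234 for the antioxidant, heat shock, purine, metal and pigment lists).

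More genes of the antibacterial response rose than fell. Of 26 genes of antimicrobial and other secreted immune peptides, 10 rose and 2 fell, and of 19 genes of peptidoglycan recognition and the Imd pathway, 11 rose and 1 fell. Adjusted over the list alone, 10 and 12 rose and 3 and 1 fell. Without control replicate 1, 8 of the peptide genes rose and 4 fell, and without tumour replicate 1, 8 of the Imd list rose and 2 fell. Besides AttD and DptA, AttA rose from 2.36 ± 0.839 to 28 ± 5.0 CPM and AttB from 2.98 ± 0.991 to 31.9 ± 5.95 CPM, near-identical neighbours whose reads cannot be told apart with certainty. PGRP-SB1 (FBgn0043578, chromosome 3L, 16727299 to 16727989) rose 9.41-fold, PGRP-SD 13.6-fold and pirk, a negative regulator of the Imd pathway, 5.18-fold (adjusted p = 9.00e-05, 1.63e-04 and 9.72e-05). The camera test gave an adjusted p of 2.83e-05 for the peptides and 2.79e-05 for the Imd list. The adjusted p of camera was 0.50 for both with an estimated correlation. The estimate itself was 0.154 for the peptides and 0.045 for the Imd list, against the preset 0.01. In the same libraries markers of fat body and haemocytes gave 1 rise and 6 falls among 20.

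**Figure D2:**
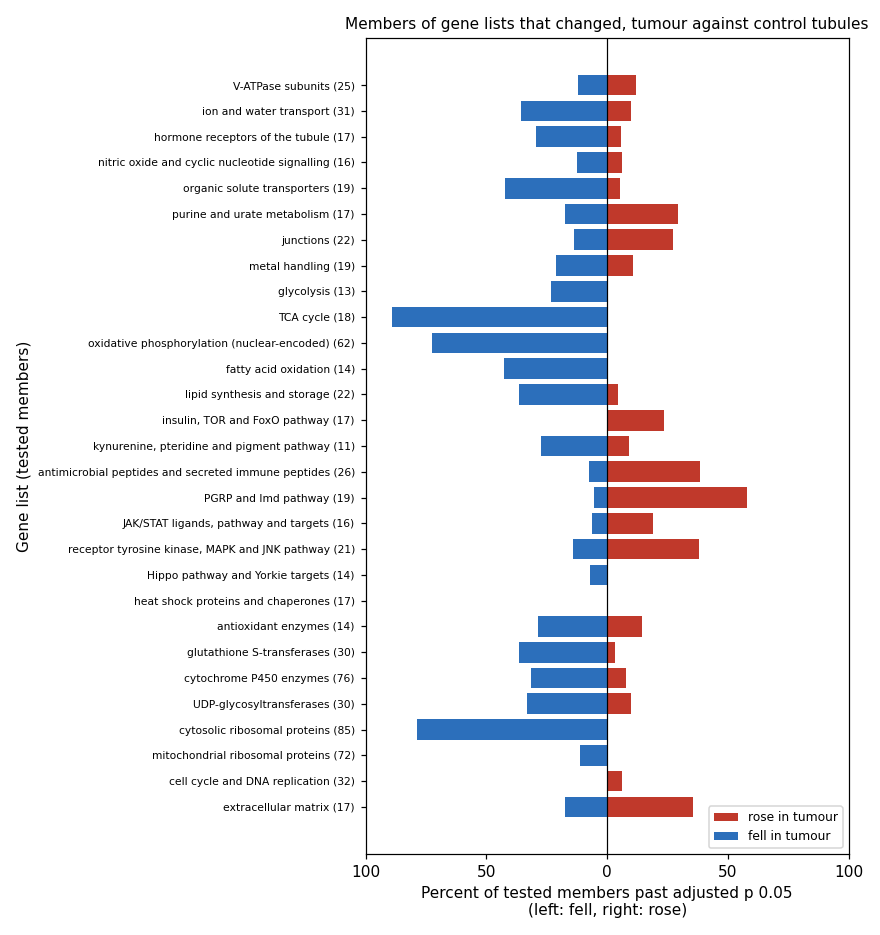
Percent of the tested members of each list of functions that passed an adjusted p of 0.05, with members that fell in tumour tubules drawn to the left and those that rose to the right; the number of tested members stands beside each name. Of 18 TCA cycle genes 16 fell, and of 19 Imd pathway genes 11 rose.

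Signalling and structural lists moved in part and none of them passed the camera test. Of 21 genes of receptor tyrosine kinase, MAPK and JNK signalling 8 rose and 3 fell; the EGF receptor antagonist gene aos rose 3.13-fold and the ligand gene spi 1.5-fold. The JAK/STAT list gave 3 rises and 1 fall among 16, with upd2 down 4.52-fold and Tep4 up 2.99-fold, and Socs36E, a target of the pathway, was at 437 ± 222 and 445 ± 179 CPM in control and tumour libraries (adjusted p = 0.974). Leaving out any library other than control replicate 2 gave between 3 and 5 rises for the kinase list, and 0 of its genes fell in the edgeR test without control replicate 3, tumour replicate 1 or tumour replicate 3. Among 17 insulin and TOR pathway genes 4 rose and 0 fell, Akt by 1.83-fold, and the insulin antagonist gene ImpL2 was at 9.97 ± 2.18 and 11.2 ± 2.67 CPM (adjusted p = 0.657). The 4 rises of the insulin list were 2 without control replicate 3 and 1 without tumour replicate 2 or 3. Hippo pathway genes gave 0 rises and 1 fall among 14, and 4 rises and 1 fall with library totals alone. In the JAK/STAT list 3 genes fell without tumour replicate 2. Library totals alone gave 6 rises in the JAK/STAT list, 6 in the insulin list, 9 in the kinase list, 9 in the matrix list and 3 in the cell cycle list, with 1, 0, 0, 3 and 0 falls in the edgeR test. Of 22 junction genes 6 rose and 3 fell: the smooth septate junction gene Ssk rose from 667 ± 77.5 to 1246 ± 180.2 CPM and pyd 2.42-fold, while Gli fell 2.51-fold. Of 17 extracellular matrix genes 6 rose and 3 fell; the laminin gene wb rose 3.88-fold, and the collagen IV gene Col4a1 and the nidogen gene Ndg fell 2.95-fold and 8.11-fold. Of 32 cell cycle genes 2 rose, RnrS by 1.6-fold, and 0 fell, but without tumour replicate 3, whose cell cycle and germline transcripts stood above those of the other tumour libraries, 10 fell and 2 rose (camera, adjusted p = 0.00218; adjusted p = 0.504 with an estimated correlation). Without any 1 of the control replicates 1 cell cycle gene rose. Adjusted over the list alone, 0 Hippo genes, 4 junction genes and 5 matrix genes fell, 8 matrix genes rose, and the other counts of these 7 lists were the same. The junction genes that rose numbered 15 with library totals alone. The adjusted p of the camera test for these lists was 0.506 for the kinase list, 0.631 for JAK/STAT, 0.234 for insulin and TOR, 0.972 for Hippo, 0.107 for junctions, 0.506 for the matrix and 0.683 for the cell cycle.

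Markers of midgut, fat body and eggshell, from cells that dissected tubules can carry, differed between the groups. Of 31 midgut enzyme genes 17 fell and 2 rose, of 11 fat body genes 4 fell, and of 18 germline and eggshell genes 10 fell (camera, adjusted p = 1.22e-08, 3.97e-04 and 0.00187; adjusted p = 0.50 for each with an estimated correlation). Of the germline and eggshell genes 3 fell without control replicate 1, 4 without control replicate 2 and 5 without tumour replicate 2, and of the midgut genes 26 fell without tumour replicate 2. Adjusted over the list alone the falls numbered 18, 6 and 11, and 1 fat body gene rose. With all libraries the germline markers osk, nanos, bcd, bam, vas and yl did not pass (edgeR, adjusted p between 0.440 and 0.997). In fits without 1 library the lowest adjusted p was 0.0134 for nanos and 0.0171 for yl, both lower in tumour libraries. The median log2 fold change of the germline and eggshell list was -4.82, and -0.23 over members above 0 in every library. The yolk protein genes Yp2 and Yp3 fell from 1319.6 ± 580.3 and 1777 ± 649.7 CPM to 54.2 ± 17 and 114 ± 54 CPM, and the lipophorin gene apolpp from 432 ± 232 to 31.4 ± 15.3 CPM. Mur18B, placed in the midgut list, was the most abundant transcript of the control tubules and fell from 5.13% ± 0.508 to 2.51% ± 0.253 of counts (SD, n = 3 each, adjusted p = 6.35e-04). Without Mur18B, the transcripts of these 3 lists held 0.460% ± 0.161 of the counts of control and 0.0493% ± 0.0186 of those of tumour libraries. Lists for the tubule's own principal and stellate cells did not pass, nor did that for progenitors, which holds markers of renal and intestinal stem cells. Those for enteroendocrine cells, haemocytes, muscle and neurons did not pass either. Principal cells gave 2 falls among 10 genes and stellate cells 3 among 8 (1 without control replicate 1 or tumour replicate 3, and 0 without tumour replicate 1 or 2). Progenitors gave 2 rises among 8 (zfh2 by 6.8-fold), and enteroendocrine cells 3 rises and 1 fall among 7 (Orcokinin by 6.99-fold). Haemocyte markers gave 1 rise and 2 falls among 9, with srp down 2.71-fold, muscle markers 2 and 2 among 18, and neuronal markers 1 and 0 among 9. The counts of these 7 lists were the same adjusted over the list alone, except for 3 falls among haemocyte markers. The progenitor list gave 3 rises and 2 falls without tumour replicate 3, where its median turned from 0.61 to -0.27, and 2 rises and 1 fall without tumour replicate 2. Of the muscle markers 0 fell without control replicate 1, control replicate 3, tumour replicate 2 or tumour replicate 3, 5 fell without tumour replicate 1, and 4 rose and 0 fell with library totals alone. Of the principal cell markers 2 rose and 1 fell with library totals alone, and of the progenitor markers 3 rose. Haemocyte markers gave 0 or 1 rises and 1 or 2 falls without 1 library, and neuronal markers 0 rises and 1 fall without tumour replicate 1. No marker of the male germline was expressed enough to be tested. The camera test gave an adjusted p of 0.33 for principal cells, 0.103 for stellate cells, 0.234 for progenitors, 0.221 for enteroendocrine cells, 0.234 for haemocytes, 0.506 for muscle and 0.972 for neurons. The median of a list and the direction of its camera test had opposite signs for the kinase list and the Hippo list, and the median and the mean did so for the V-ATPase, kinase, Hippo, heat shock and muscle lists.

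Across all genes the 6 libraries separated by group on the first principal component, which held 58.8% of the variance, and 46.9% of tested genes had no overlap between groups, against 10% by chance for 3 against 3. The number of genes that passed was 1769 without control replicate 3 (887 rose), and 865 rose without tumour replicate 1. With library totals alone as the scaling, which moved the median log2 fold change of all genes by 0.29, 3079 genes rose and 830 fell (78.8% of calls higher, against 53.3% with TMM). Falls outnumbered rises with RLE (1140 rose, 1403 fell), upper-quartile scaling (1182 and 1412) and DESeq2 (1340 and 1700). On library totals the medians of the V-ATPase, hormone receptor, nitric oxide, metal, pigment, kinase, heat shock, antioxidant, mitochondrial ribosomal, principal cell, muscle and neuron lists changed sign, and all directions above are relative to the TMM level. The camera test passed 14 of 39 lists in the real grouping. It passed up to 23 when the same 6 libraries were grouped in other ways. Those groupings keep part of the genotype difference, so that count does not measure false calls. The preset test is therefore given beside the counts of genes and not on its own. No list passed camera with an estimated correlation, where the lowest adjusted p was 0.50. The hormone receptor list, with an estimate of -0.036, was at 0.50 too. A value of 0.50 there therefore does not show that correlation within a list accounts for its call.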

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

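Scaling by library totals alone, leaving out the midgut and eggshell lists, list medians over members above 0 in every library, and member counts without each library or by other tools were chosen after the data were seen. The 2726 genes that passed became 816 against a fold of 1.5 and 1197 at a threshold of 0.01, fewer by construction, and 1769 to 2364 without 1 library, where 865 to 1223 rose and 882 to 1141 fell. Genes that rose numbered 336 against a fold of 1.5, 598 at 0.01 and 3079 with library totals alone, and genes that fell 480, 599 and 830. With library totals alone yki passed (log2 fold change 0.47, adjusted p = 0.015). Gene lists of functions that passed, 11, became 0 with an estimated correlation, 16 with fry and 7 with fry and a replicate block. With camera and a replicate block they stayed at 11. All 14 lists that passed with camera also passed with fry, and 5 of them with fry and a replicate block. Marker lists that passed, 3, became 2 with the filter of 5 CPM, 0 with an estimated correlation and 7 with fry. They became 0 with fry and a replicate block, and 1 where the midgut and eggshell lists were left out, by construction. Reversed values, none of which had passed with all libraries, were Socs36E -0.037 with RLE, -0.038 with upper-quartile scaling, -0.021 with the 5 CPM filter and -0.032 with DESeq2; Sting 0.25 with library totals alone, CycB -0.61 and nanos -0.97 with a replicate block, and CycB -0.48 and nanos -0.69 with limma-voom; and over fits without 1 library TkR99D -0.052 to 0.40, Nos -0.28 to 0.56, ImpL2 -0.0070 to 0.28, Socs36E -0.35 to 0.52, Sting -0.11 to 0.0049, CycB -1.67 to 0.97 and nanos -2.07 to 0.62. The lowest values of CycB and nanos were without tumour replicate 3 and passed. The cause was not tested except where construction gives it. Of all values for named genes 1805 kept their direction and side of the threshold, 44 lost and 3 gained a call, and 19 reversed; of those for lists that passed, 212 kept and 24 lost their call. Same-numbered libraries did not deviate together (r across genes 0.08, -0.08 and 0.06; genes are not independent), and a replicate block gave 2538 genes. Depth limits changes in genes near 0.0866 CPM.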

Other observations

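The pathways and the tests of explanations below, and the count of lists over other groupings of the libraries, were chosen after the results were seen; the lists, the edgeR results of yki and esg and the count of genes over other groupings were planned. Of 31 tested genes of valine, leucine and isoleucine degradation, 23 fell and 0 rose, with a median log2 fold change of -1.04. In the same libraries 17 of 31 midgut and 4 of 11 fat body markers fell. Gabat, the GABA transaminase gene, fell from 865 ± 238 to 113 ± 22.8 CPM (SD, n = 3 each), and CG6638 and BckdhA, a subunit gene of the branched-chain ketoacid dehydrogenase, fell 3.47-fold and 2.5-fold. Of 38 proteasome genes 29 rose and 0 fell, among them Prosalpha7 (1.8-fold) and Rpn10 (1.63-fold); 17 rose without control replicate 2, 13 without control replicate 3 and 14 without tumour replicate 1. Of 65 genes of ribosome biogenesis 39 rose, among them NHP2 (2.09-fold); 22 rose without control replicate 1, 13 without tumour replicate 1 and 24 without tumour replicate 3. Camera gave an adjusted p of 6.91e-14, 1.64e-08 and 4.42e-06 for the 3 pathways among 263 tested, and an adjusted p of 0.564 with an estimated correlation was the lowest of any pathway. Of the 263 pathways 66 passed with camera at the preset correlation, so passing does not set these 3 apart.

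Of 13 tested mitochondrially encoded mRNAs 9 fell and 0 rose by edgeR, with a median log2 fold change of -1.11. The cytochrome oxidase gene mt:CoI fell 2.08-fold and the cytochrome b gene mt:Cyt-b 2.19-fold. Srg2 rose from 6.12 ± 0.792 to 143 ± 14.6 CPM, as Nazo did, while Sting was at 34.2 ± 3.11 and 33.4 ± 2.75 CPM in control and tumour libraries (adjusted p = 0.856, edgeR).

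Of 165 genes of the TCA cycle, oxidative phosphorylation and ribosomal proteins 128 fell in tumour tubules, and the median loss over all 165 was 31.7%. Part of it may come from RNA of midgut, fat body and ovary in control libraries. That part cannot be told apart from a change in the tubule. The marker transcripts of these tissues held 5.59% of control counts, with Yp2 at 1319.6 ± 580.3 CPM among them. Without Mur18B, which the tubule may itself express, they held 0.460% of control and 0.0493% of tumour counts. Mur18B did not fall in step with them, from 5.13% ± 0.508 to 2.51% ± 0.253 of counts. The share of the other transcripts of those tissues is not known. The tables argue against a common scaling factor as the whole cause. Of the genes, 96.4% lay below the median of other genes of like expression. Their median log2 difference was -0.30 (SD 0.29, so by a narrow margin), smaller than their median log2 fold change of -0.55. Camera had already called these lists lower than other genes, so this comparison is not an independent test. Genes within each list moved together (estimated correlation 0.66, 0.71 and 0.86), so the SD over genes does not measure the spread between libraries. The size of the fall depends on scaling: with library totals alone 60 fell, 3 rose and the median loss was 17%. A response of the tubule to the tumour and expression of yki3SA in the tubule itself stay open. Any difference in rearing and any other difference between the genotypes stay open too. None of these was tested.

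In tumour replicate 3 all 32 cell cycle genes were above the mean of the other tumour libraries, with a median log2 ratio of 2.13. Germline RNA in that library may account for this: 6 of 7 germline markers were higher there, with a median of 3.26, and yl was at 8.14, 2.74 and 45.9 CPM in tumour replicates 1, 2 and 3. The 7 are the tested members of the germline and eggshell list without its eggshell genes. The eggshell genes Vm26Aa and Cp36 were not higher there. They were at 2.37, 0.635 and 0.0172 CPM and at 0.871, 0 and 0.0172 CPM in tumour replicates 1, 2 and 3. Dividing progenitors of the tubule stay open. Of the 8 tested markers of renal and intestinal stem cells, esg, N, Sox21a, Sox100B and zfh2 were picked for this test. Of these, 1 of 5 was above 0, with a median of -0.82 (SD 1.29). That median lay at percentile 0.14 of 10000 random lists matched on expression. The whole list of 8, which also holds the cell cycle gene polo, moved the other way. Its median log2 fold change of tumour over control was 0.61 with tumour replicate 3 and -0.27 without it. In control replicates 1, 2 and 3 yl was at 41.3, 37.4 and 50.02 CPM, nanos at 3.9, 2.95 and 3.49 CPM against 1.06, 0.59 and 9.48 CPM in the tumour replicates, and CycB at 64.6, 54.3 and 65 CPM against 23, 15.6 and 217 CPM.

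The rise of antibacterial peptide and Imd pathway genes could come from fat body RNA in tumour libraries. The 3 most expressed fat body markers, all yolk protein genes, fell, with a median log2 fold change of -3.96. This argues against it unless the fat body itself made less of them or another tissue supplied them in control libraries. Of all 11 fat body markers 4 fell, apolpp among them, and 0 rose, or 6 and 1 adjusted over the list alone. The list median was -1.72, and 63.6% of members were lower, so the argument rests mainly on 1 gene family. Haemocyte RNA cannot be told apart, since the 3 most expressed haemocyte markers went both ways, with a median of -0.073. RNA of the tumour-bearing gut cannot be told apart from the tubule's own, since yki differed by 0.18 and the tubule's own yki would hide a small share. Transcripts of the midgut, progenitor and enteroendocrine lists went both ways. Of 31 midgut enzyme genes 17 fell and esg did not pass with all libraries, while zfh2 and Orcokinin rose 6.8-fold and 6.99-fold. The progenitor list, with esg and zfh2, holds markers of renal as well as intestinal stem cells. Expression of yki3SA in the tubule itself is also confounded with genotype, as is any difference in rearing or in exposure to microbes. None of these was tested.

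With 3 libraries in each group there are 10 groupings, too few for a share under 0.05. The real grouping gave 2726 genes and the highest of the others 0 (edgeR), so that 1 of 10 reached the real count. For lists the real grouping gave 14, the highest of the others 23, and 4 of 10 reached the real count. Each other grouping sets libraries of both genotypes in 1 group, which widens its spread and lowers the number of genes that can pass.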
